A study of Mus musculus with 20 samples.

How the data were processed

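Bulk mRNA sequencing was done on mouse embryonic stem cells grown, per the labels, in serum with LIF and the 2i inhibitors. The 20 libraries fall into 2 systems. In the conditional system, cells carrying a floxed Trim71 allele (Trim71-cond) were set against cells in which the gene was deleted (Trim71-KO), with 4 libraries each carrying the replicate codes 1A, 2B, 3A and 3B. In the clonal system, 3 WT clones (C16, C7, C5), 3 clones homozygous for the R595H change of TRIM71 (C14, C20, C24) and 3 heterozygous clones (R595H/+; C15, C21, C23) were sequenced. Clones C16, C14 and C15 have a library from each of 2 dates, 20/1 and 5/2, and the other clones have one from 5/2. The labels name TRIZOL extraction of total RNA, a poly(A) library kit (TruSeq RNA v2) and paired-end sequencing.

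The deposited table holds values on a log2 scale for 13283 gene symbols, one column per library, scaled between libraries by the authors before deposit. The notes of the authors name CASAVA 1.8, STAR and DESeq2. The genome build, the annotation, the counting step and the transformation are not given in the sources used here. The values run from -0.65 to 18.0 with 1.58% of them below 0. They were inferred to be like regularized log values, in which low values are drawn toward their mean over the libraries. Base 2 was inferred from DESeq2, whose transformations use it, and is not stated in the table, so every fold printed here rests on that inference. Such shrinkage, which was not measured, would understate the fold changes of genes with low values. Read counts cannot be recovered from such values, so the depth of each library is unknown, no interval that needs it is given, and the total of the back-transformed values is not a depth.

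The plan had assumed normalized values on a linear scale, to be logged with an added constant of 1. Because the table was already on a log scale, limma 3.58.1 in R 4.3.3 was run on the values as deposited, and the minimum mean of 10 became a mean of at least 3.32 on the log2 scale. Genes were fitted with lmFit and eBayes with trend and robust set, and called at a Benjamini-Hochberg adjusted p under 0.05. The conditional system had its own fit of 8 libraries. The libraries of one clone were averaged first, so that the clonal fit held 9 clone values, 3 per genotype, with one estimate of the spread. Comparisons were Trim71-KO against Trim71-cond, each of the R595H genotypes against WT, R595H/R595H against R595H/+, and the Trim71-KO effect minus the R595H/R595H effect in one fit of both systems. The 2 systems differ in their starting cells and handling as well as in genotype, and that last test cannot separate these.

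Before the data were examined, 28 gene lists were fixed from knowledge of embryonic stem cells and TRIM71. A list was tested where at least 5 members passed the filter, which held for 23. The lists covered naive pluripotency, formative and primed pluripotency, neural progenitor, neuronal, endoderm and primitive endoderm, germ line, reported TRIM71 targets, let-7 targets, the microRNA pathway, p53 targets, MAPK response, Wnt response, BMP and TGF-beta response, the Notch pathway, Polycomb and chromatin regulators, S phase, G2/M phase, imprinted genes, immediate early and stress genes, hypoxia and glycolysis, mitochondrially encoded genes, cytosolic ribosomal proteins, and lipid and cholesterol synthesis. Lists for mesoderm, trophectoderm, the two-cell-like state, fibroblasts or feeders, and the Y chromosome with Xist had too few members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes.

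Genes were named by a rule fixed at the same time. It took Trim71, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 50 on the linear scale, up to 4 members of each list with the smallest p, the 10 genes per direction called in both systems with the largest smaller change, and the 5 per direction with the smallest p of the difference. Predicted genes were passed over. Part of the genes so chosen are named in the text. Positions are from GENCODE vM21 on GRCm38, in which 13156 of the symbols were found once, 24 more than once and 103 not at all.

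The level of Trim71 was compared with a two-sided exact permutation test, which cannot go below 0.0286 with 4 against 4 libraries or below 0.1 with 3 against 3 clones. Fold changes of the 2 systems were correlated across genes, which are not independent replicates. A correlation between the R595H/R595H and R595H/+ effects arises from the shared WT clones alone, so it was set beside 100 simulations of unchanged groups. Seed matches of let-7 (CTACCTC) and of the miR-290 family (GCACTTA) were counted in annotated 3' UTRs and tested with 10000 permutations within 10 bins of UTR length. No other form of either site was counted.

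The first digit of a replicate code is the day tag of the labels. The residual correlation of libraries sharing a code was -0.890 for 1A, -0.089 for 2B, -0.117 for 3A and 0.130 for 3B. The code was used as a block only as an alternative. The negative value of 1A means that its 2 libraries deviated from their group means in opposite directions. Within C14, the libraries of the 2 dates lay far closer together than any other pair of one group, with a robust SD of 0.024 over the 1557 genes with a mean of at least 8, against 0.124 for C16, 0.128 for C15 and a median of 0.118 over 30 pairs. Whether they are separate cultures is not known, and averaging by clone counted them once. The next closest pairs were C14 with C24, 2 R595H/R595H clones, at 0.071 and 0.076, closer than the libraries of C16 or of C15, while C20 with C24 was at 0.205. Being closer than the libraries of C16 or of C15 was not particular to C14 and C24. WT C16 (20/1) with R595H/+ C15 (5/2), of different genotypes, was at 0.093. Whether C14 and C24 share descent is not known, and the tests counted them as independent clones.

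The pipeline was tested on simulated data with changes planted in 200 genes, and the shares called hold for that number. With 4 libraries per group, 25.4%, 85.1% and 98.5% of genes with true log2 changes of 0.25, 0.5 and 1 were called, and with 3 clones 2.99%, 71.6% and 90.9%. Of the unchanged genes, 2 of 9355 and 10 of 9356 were called. The simulated noise was independent between genes and between samples, so these shares leave out correlation between genes and closeness between clones.

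Alternatives covered the filter, the scaling between libraries, the replicate code as a block, one fit of all libraries, the clone as a random block, the date, every library as a separate replicate, a minimum fold, the correlation used by camera and leaving out each library or clone. Covariates for the Lars2 value and for the mean of 4 Y-linked genes, and list tests with equal library totals or recomputed median-of-ratios factors, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.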

Results

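Transcript levels were measured in mouse embryonic stem cells that lacked TRIM71, an RNA-binding protein of pluripotent cells, or carried its R595H form. There were 4 Trim71-cond and 4 Trim71-KO libraries, and 3 clones each of WT, R595H/+ and R595H/R595H in 12 libraries. The title of the series asks how alike the deletion and the homozygous change are, and names neural differentiation. Library medians lay between 5.15 and 5.20 on the log2 scale of the deposited values, and the depth of each library is unknown. Lars2 alone held between 0.334% (R595H/R595H C20) and 13.2% (R595H/R595H C24) of the back-transformed sum of a library. The mean of 4 Y-linked genes was 5.65 or more in every conditional library. It was 6.00 in WT C5, 4.08 in WT C7, and 4.31 (20/1) and 3.89 (5/2) in WT C16. In the R595H/R595H libraries it lay between 3.72 and 4.36.

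Trim71 itself, on chromosome 9 from 114507133 to 114564369 (GRCm38, minus strand, 4 exons), was 2.80-fold lower in Trim71-KO than in Trim71-cond. The level was 7.47 ± 0.05 (SD, n = 4) against 8.95 ± 0.04 (SD, n = 4), with a two-sided exact permutation p of 0.0286, the smallest the design allows. In the clones the transcript stood 1.53-fold higher in R595H/R595H, at 10.11 ± 0.10 (SD, n = 3) against 9.50 ± 0.03 (SD, n = 3) in WT. The exact permutation p was 0.1, the smallest possible with 3 against 3 clones, while limma gave an adjusted p of 0.00063. R595H/+ clones were at 9.58 ± 0.04 (SD, n = 3), a log2 difference of 0.08 from WT with an exact permutation p of 0.1, again the smallest possible, and a limma adjusted p of 0.83. The exact p of R595H/R595H against R595H/+ was 0.1 as well. The arginine codon that R595H changes, in exon 4, lies at 114513428 to 114513430. Which part of the gene was deleted is not given in the labels, so the signal left in Trim71-KO says nothing about intact transcript.

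**Figure D1:**
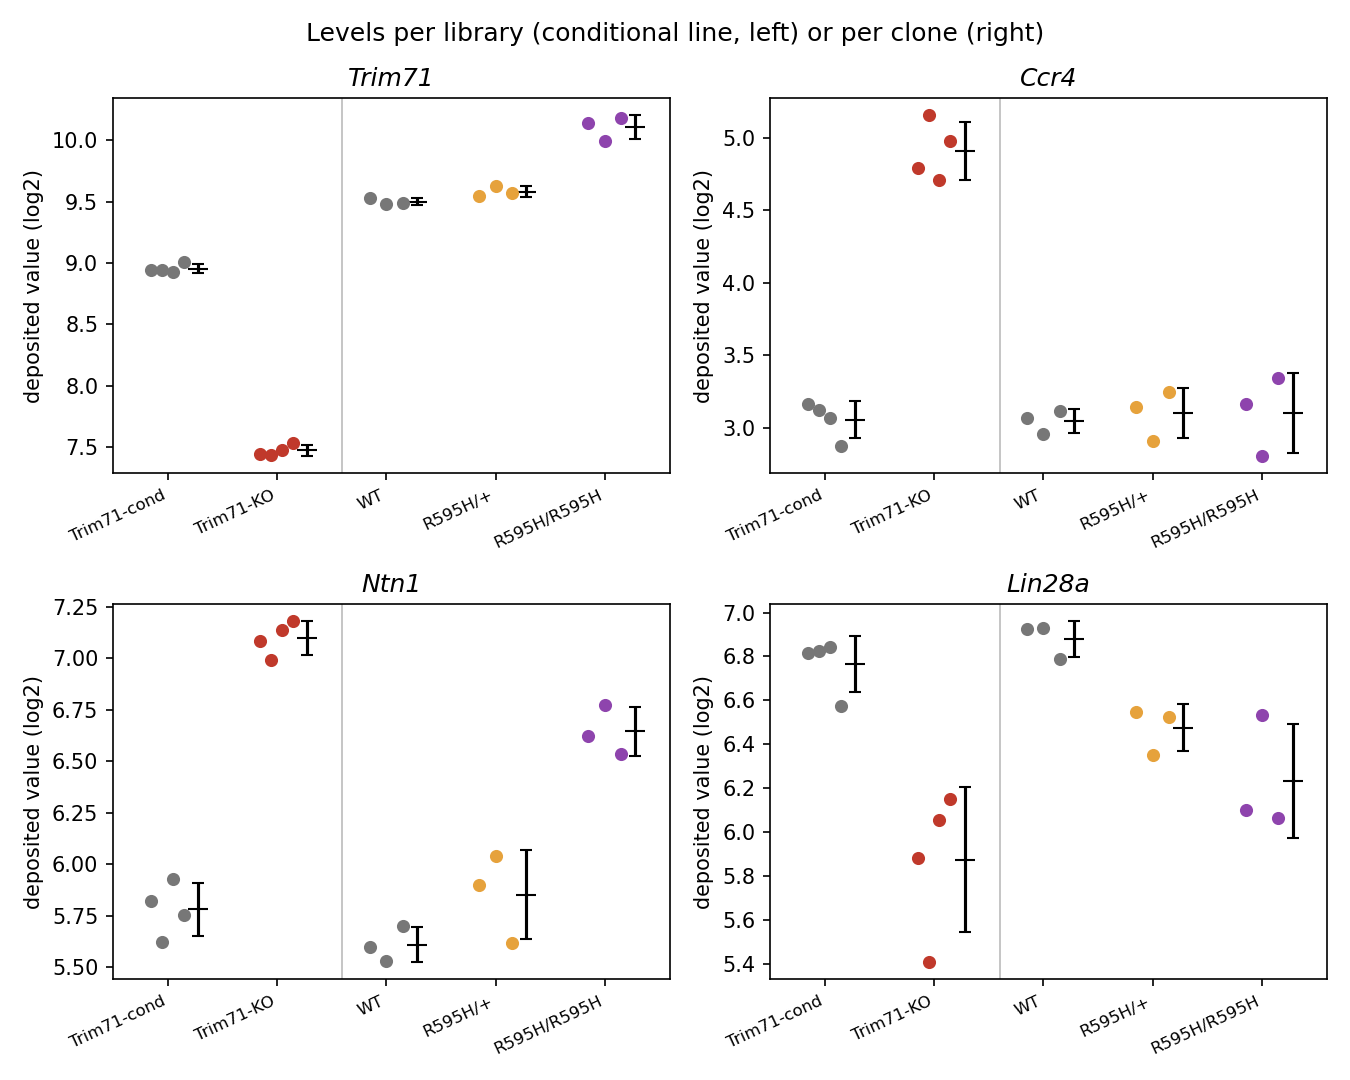
Deposited values (log2) of Trim71, Ccr4, Ntn1 and Lin28a by group, one point per Trim71-cond or Trim71-KO library or per clone, with the mean and SD as bars. Trim71 averaged 7.47 in Trim71-KO against 8.95 in Trim71-cond, and 10.11 in R595H/R595H against 9.50 in WT.

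In Trim71-KO cells Ntn1, which encodes the guidance cue netrin-1, was 2.49-fold higher (log2 1.32 ± 0.08, SE, n = 4 against 4). Txnip, an inhibitor of thioredoxin, rose by 1.23 ± 0.19 on the log2 scale, the transcription factor Nfib by 0.87 ± 0.08, the semaphorin receptor Plxnb2 by 0.86 ± 0.07, Pros1 (protein S) by 0.82 ± 0.10 and the pluripotency factor Klf4 by 0.74 ± 0.07. The chemokine receptor gene Ccr4, the next gene downstream of Trim71 on the same strand, rose by 1.85 ± 0.10. Its level was low enough that it was not tested in the clones alone. Lefty1, an antagonist of Nodal signalling, fell by 1.24 ± 0.09, the ubiquitin ligase gene Rnf213 fell by 1.05 ± 0.10 and Lin28a, which blocks maturation of let-7, fell by 0.89 ± 0.12. Ccne1 (cyclin E1) fell by 0.80 ± 0.08, Dusp9, a MAPK phosphatase, fell by 0.68 ± 0.09, and the de novo DNA methyltransferase gene Dnmt3a fell by 0.67 ± 0.09. Adjusted p-values of these genes from limma ranged up to 0.0055 for Txnip.

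Across the genome limma called 1783 of 9580 genes, 885 higher and 898 lower in Trim71-KO, with 3129 at an unadjusted p under 0.05. The labels name no clone for these libraries, and whether they stem from separate deletions is not known. The p-values therefore measure the spread between libraries, which may be less than that between independent deletions. Most changes were small: the median size among called genes was 0.29 on the log2 scale, 60 genes passed 1.5-fold (38 higher, 22 lower) and 6 passed 2-fold. Groups did not overlap for 20.8% of genes, where chance gives 2.86%. The effect was smaller between the 2 libraries of code 1A, in a test chosen after the values were seen. Genes called from the other codes had medians there of 0.18 (740 higher) and -0.12 (755 lower), against at least 0.25 and at most -0.24 when another code was held out. Among Y-linked genes, some also fell in Trim71-KO, Zfy1 by 0.53 ± 0.09, Ddx3y by 0.40 ± 0.07 and Uty by 0.40 ± 0.09.

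Of the naive pluripotency genes, 10 rose and 3 fell among 24 tested (11 and 3 adjusted over the list alone). Klf4, Nr5a2 (0.52 ± 0.06) and Nanog (0.39 ± 0.05) rose, while Sall4 fell by 0.46 ± 0.06, and the list as a whole was higher (adjusted p 0.00085, and adjusted p = 0.069 with an estimated correlation). Targets of p53 were higher, with 12 risen and 4 fallen of 22 (13 and 4 adjusted over the list alone). Trp53inp1 (0.51 ± 0.05), the cyclin gene Ccng1 (0.51 ± 0.06), the death receptor gene Eda2r (0.73 ± 0.09) and Polk (0.50 ± 0.07) were among the risen. The adjusted p of that list was 3.4e-05, and 0.049 with an estimated correlation, the only list to pass with it. Of reported TRIM71 targets, 3 rose and 1 fell of 7, the same adjusted over the list alone: Plxnb2, the splicing regulator Mbnl1 (0.57 ± 0.06) and Rbl1 (0.32 ± 0.07) rose and Kdm1a fell by 0.16 ± 0.05 (adjusted p 0.056 with the replicate block). The list gave an adjusted p of 0.0016, and adjusted p = 0.20 with an estimated correlation.

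Genes of S phase were lower: 11 of 22 fell and 0 rose (14 and 0 adjusted over the list alone). Beside Ccne1, the helicase subunits Mcm3, Mcm5 and Mcm2 fell by 0.41 ± 0.05, 0.37 ± 0.06 and 0.32 ± 0.06 (adjusted p of the list 2.0e-07, and adjusted p = 0.21 with an estimated correlation). Hypoxia and glycolysis genes were lower too, with 8 of 19 fallen and 0 risen (12 and 0 adjusted over the list alone). Ldha fell by 0.38 ± 0.07, Aldoa by 0.30 ± 0.05 and Hk2 by 0.25 ± 0.05 (adjusted p of the list 3.4e-05, and adjusted p = 0.37 with an estimated correlation). Lipid and cholesterol synthesis had 5 of 23 fallen and 0 risen, the same adjusted over the list alone, among them Hmgcs1 (fell by 0.29 ± 0.05) and Insig1 (fell by 0.27 ± 0.06), at an adjusted p of 0.013 (adjusted p = 0.37 with an estimated correlation). Mitochondrially encoded genes had 2 of 7 risen and 0 fallen (4 and 0 adjusted over the list alone), mt-Co1 by 0.39 ± 0.05 and mt-Nd4 by 0.27 ± 0.08, at an adjusted p of 0.00085 (adjusted p = 0.37 with an estimated correlation). Under quantile normalization the mt-Co1 change was 0, because that gene held the same rank in each of the 8 libraries. The call of mt-Nd4 was lost in 4 alternatives. By fry, of the lists camera called, naive pluripotency (adjusted p 0.00024), p53 targets (0.00014), TRIM71 targets (0.00024), S phase (0.0033) and lipid synthesis (0.028) passed in the same direction, and hypoxia (0.055) and mitochondrial genes (0.080) did not.

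Neural genes went both ways in Trim71-KO. Of 10 neural progenitor genes tested, 3 rose and 1 fell (5 and 2 adjusted over the list alone): the transcription factors Olig2 (0.50 ± 0.10), Sox11 (0.43 ± 0.09) and Hes1 (0.29 ± 0.09) rose, and Cdh2 (N-cadherin) fell by 0.59 ± 0.08. The call of Hes1 was lost in 6 alternatives. Of 12 neuronal genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone): the neurofilament gene Nefm rose by 0.57 ± 0.09, the axonal gene Dpysl3 fell by 0.76 ± 0.09 and the sodium channel gene Scn3a fell by 0.28 ± 0.09 (adjusted p 0.053 with the replicate block). Neither list passed by camera or fry, at camera adjusted p-values of 0.25 and 0.76. Formative and primed genes had 2 risen and 4 fallen of 13 (3 and 4 adjusted over the list alone, adjusted p 0.25), with the tight junction gene Cldn6 risen by 0.64 ± 0.08 and Dnmt3a and Lin28a fallen. Among let-7 targets 1 rose and 4 fell of 16 (1 and 5 adjusted over the list alone, camera adjusted p 0.25, and 0.0033 by fry for lower): Lin28b rose by 0.44 ± 0.09 while Lin28a and Cdc25a (fell by 0.36 ± 0.07) were lower. Of 25 Polycomb and chromatin regulators 4 rose and 4 fell (5 and 4 adjusted over the list alone, adjusted p 0.67), with Tet2 risen by 0.39 ± 0.05, Uhrf1 fallen (fell by 0.49 ± 0.06) and Ezh2 fallen (fell by 0.39 ± 0.07).

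The other lists did not pass by camera in Trim71-KO. By fry, BMP and TGF-beta response genes passed as lower (adjusted p 0.019), and MAPK response and Notch pathway genes as higher (0.032 each). Endoderm genes had 3 risen and 1 fallen of 6 (3 and 2 adjusted over the list alone, adjusted p 0.42), germ line genes 1 and 1 of 16 (1 and 1, adjusted p 0.26), the microRNA pathway 3 and 1 of 15 (3 and 1, adjusted p 0.67) and MAPK response genes 2 and 0 of 8 (2 and 0, adjusted p 0.25). Wnt response genes had 0 risen and 2 fallen of 7 (0 and 2, adjusted p 0.59), with a median of 0.03 and a mean of -0.08. BMP and TGF-beta response genes had 3 and 2 of 12 (3 and 3, adjusted p 0.56), Notch pathway genes 3 and 0 of 7 (4 and 0, adjusted p 0.054) and G2/M genes 3 and 5 of 24 (3 and 5, adjusted p 0.36). Imprinted genes had 2 and 1 of 11 (2 and 1, adjusted p 0.78), immediate early and stress genes 2 and 0 of 16 (2 and 0, adjusted p 0.28), and cytosolic ribosomal protein genes 3 and 1 of 39 (1 and 1, adjusted p 0.59). Lists for mesoderm, trophectoderm, the two-cell-like state and fibroblasts had 1, 4, 2 and 3 members above the filter, and the Y-linked list had 4, so they were not tested.

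The comparison of R595H/R595H with WT asked what the homozygous change does in clones. Ntn1 rose by 1.03 ± 0.11 on the log2 scale (SE, n = 3 clones against 3), and was the only gene past 2-fold. The imprinted gene Peg10 rose by 0.97 ± 0.14, the ephrin receptor gene Epha4 by 0.92 ± 0.12, the peroxisomal transporter gene Abcd3 by 0.86 ± 0.07, Plxnb2 by 0.79 ± 0.09 and the cholesterol transporter gene Abca1 by 0.77 ± 0.09. The protease inhibitor gene A2m fell by 0.95 ± 0.16, Rnf213 fell by 0.83 ± 0.11, Lin28a fell by 0.65 ± 0.11, and the germ line helicase gene Ddx4 fell by 0.52 ± 0.09. Adjusted p-values of these genes from limma reached at most 0.0091.

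In all, limma called 328 of 9588 genes, 210 higher and 118 lower in R595H/R595H, with 2021 at an unadjusted p under 0.05. Among them 32 passed 1.5-fold, 26 higher and 6 lower. Clones did not overlap for 29.7% of genes, against 10% by chance. The count moved with single clones, from 67 without R595H/R595H C14 to 541 without R595H/+ C21, which enters through the shared spread, and 14 of the 38 called genes named here kept their call without each clone in turn (Ntn1, Plxnb2, Abcd3, Rnf213 and Peg10 among them, Lin28a and A2m not). The count was 134 with the mean of the Y-linked genes as a covariate, low in each R595H/R595H clone and also in WT C16 and C7. It was 158 (72 higher, 86 lower) with each library scaled to the same total, where the median change of all tested genes moved by -0.035. The total was highest in R595H/R595H C24 and lowest in R595H/R595H C20, the libraries with the highest and lowest share of Lars2.

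Immediate early and stress genes were the list with the smallest p in R595H/R595H, with 2 of 16 risen and 0 fallen (4 and 0 adjusted over the list alone): Gadd45a rose by 0.68 ± 0.11 and Asns, of the amino acid response, by 0.42 ± 0.08. Its adjusted p was 0.00037 (adjusted p = 0.082 with an estimated correlation). Targets of p53 had 3 of 22 risen and 0 fallen (7 and 1 adjusted over the list alone), Eda2r by 0.61 ± 0.14, Phlda3 by 0.47 ± 0.10 and Perp by 0.37 ± 0.10, at an adjusted p of 0.00999 (adjusted p = 0.31 with an estimated correlation). Naive pluripotency genes had 3 of 24 risen and 0 fallen (4 and 0 adjusted over the list alone), Tet2 by 0.53 ± 0.07, Klf4 by 0.47 ± 0.07 and Tbx3 by 0.29 ± 0.07 (adjusted p 0.032, and adjusted p = 0.31 with an estimated correlation). Endoderm genes had 2 of 6 risen, the same adjusted over the list alone, the basement membrane genes Lama1 (0.58 ± 0.08) and Col4a2 (0.49 ± 0.12), at an adjusted p of 0.032 (adjusted p = 0.36 with an estimated correlation). Germ line genes were lower as a list, with 1 risen and 2 fallen of 16 (1 and 4 adjusted over the list alone): Piwil2 rose by 0.51 ± 0.09, and Ddx4 and Mael (fell by 0.38 ± 0.09) were lower, at an adjusted p of 0.031 (adjusted p = 0.36 with an estimated correlation). Between R595H/R595H and R595H/+ the germ line list was not called (camera adjusted p 0.78). Ddx4 averaged 5.79 in WT, 5.36 in R595H/+ and 5.26 in R595H/R595H.

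Lipid and cholesterol synthesis genes were lower, with Stard4 (fell by 0.50 ± 0.12) the 1 member of 23 to pass, also over the list alone, at an adjusted p of 0.00999 (adjusted p = 0.38 with an estimated correlation). Hypoxia and glycolysis genes were lower with 0 of 19 passing (0 risen and 2 fallen adjusted over the list alone, adjusted p 0.032, and adjusted p = 0.64 with an estimated correlation). Notch pathway genes were higher with 0 of 8 passing (2 risen and 0 fallen adjusted over the list alone, adjusted p 0.032, and adjusted p = 0.36 with an estimated correlation), a call lost under quantile normalization (adjusted p 0.052). The neuronal list had 2 risen and 0 fallen of 12 (2 and 1 adjusted over the list alone), Nefm by 0.71 ± 0.11 and Syt11 by 0.30 ± 0.08, and missed the threshold at an adjusted p of 0.062. Both genes lay near the filter of 3.32, with WT means of 3.49 for Nefm and 3.40 for Syt11. Of 10 neural progenitor genes 0 passed (1 and 1 adjusted over the list alone, adjusted p of the list 0.63), Olig2 standing 0.42 ± 0.12 above WT at an adjusted p of 0.061. S phase genes, at 0 of 22 either way (0 adjusted over the list alone), gave an adjusted p of 0.062. Among BMP and TGF-beta response genes 3 of 13 fell and 0 rose (1 risen and 3 fallen adjusted over the list alone, adjusted p of the list 0.055), with both Nodal antagonists lower, Lefty2 (fell by 0.73 ± 0.16) and Lefty1 (fell by 0.56 ± 0.10). Formative and primed genes had 2 risen and 2 fallen of 13 (5 and 3 adjusted over the list alone, adjusted p of the list 0.61), among them Dnmt3b (rose by 0.47 ± 0.11) and Sox4 (fell by 0.53 ± 0.09). Imprinted genes had 1 and 1 of 11, the same adjusted over the list alone (adjusted p of the list 0.63), Peg10 risen and Slc38a4 fallen (fell by 0.45 ± 0.09). With the 5/2 libraries only, the neuronal (0.046), S phase (0.050), BMP and TGF-beta response (0.045) and reported TRIM71 target lists (0.046, against 0.062 with both dates) passed, and the neuronal (0.047), BMP and TGF-beta response (0.032) and TRIM71 target (0.032) lists also passed with equal library totals. With a correlation estimated in those same fits, each of these calls was lost (adjusted p = 0.31 or more with an estimated correlation). By fry, adjusted p-values were 0.0021 for stress genes, 0.019 for naive pluripotency, 0.068 for p53 targets and at least 0.086 for the other lists that camera called, while TRIM71 targets and BMP and TGF-beta response genes passed (0.019 each).

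**Figure D2:**
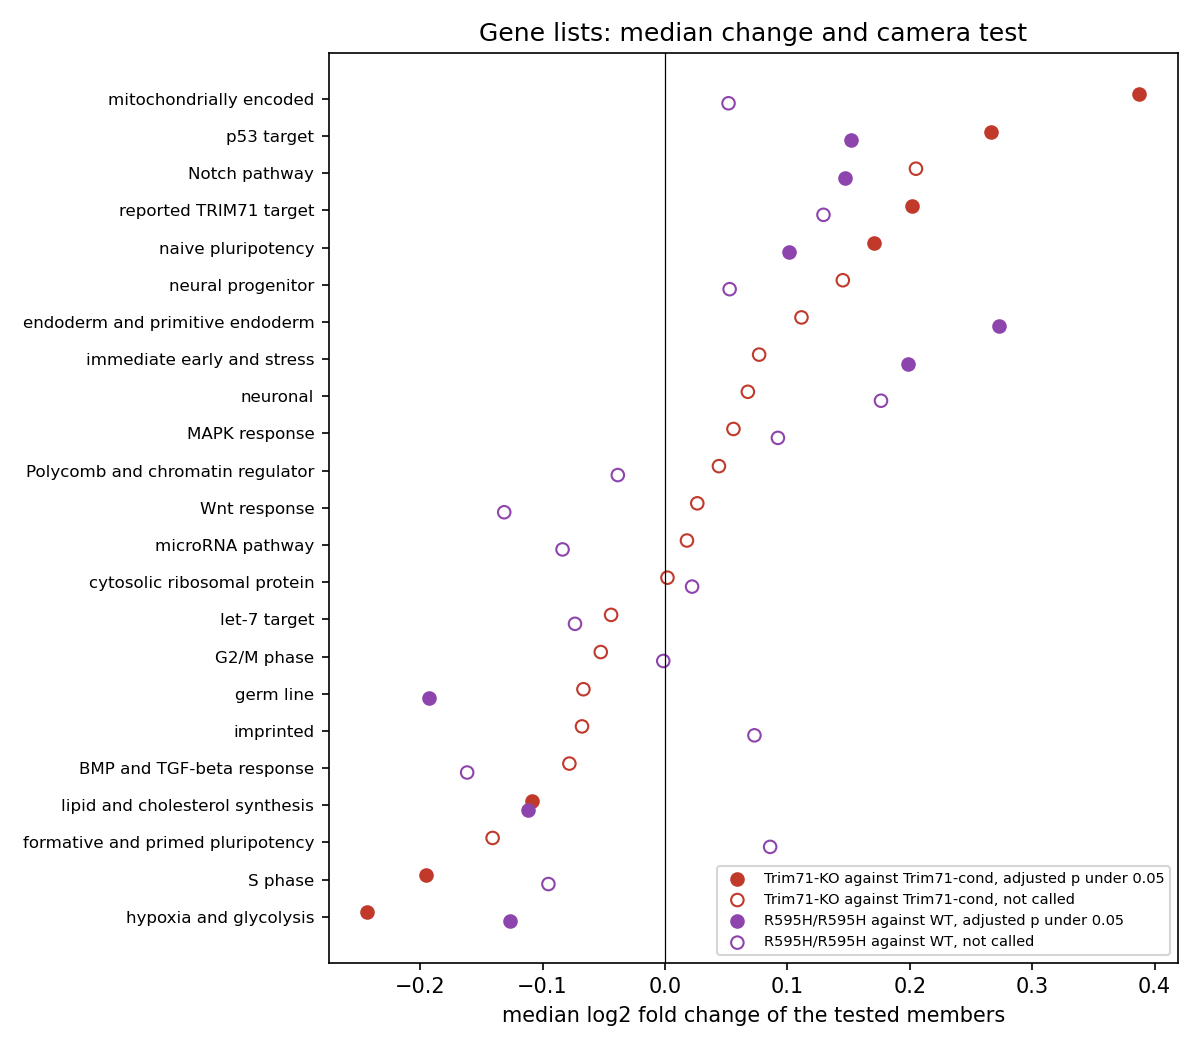
Median log2 fold change of each tested gene list in Trim71-KO against Trim71-cond and in R595H/R595H against WT, filled where the camera adjusted p was under 0.05 at the preset correlation. The p53 target list had medians of 0.27 and 0.15, and the S phase list -0.20 and -0.10.

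The heterozygous clones asked whether one changed allele was enough. Limma called 0 of 9588 genes in R595H/+ against WT, with 736 at an unadjusted p under 0.05, and clones did not overlap for 12.5% of genes against 10% by chance. With 3 clones per group and 200 genes changed in the simulation, 71.6% of changes of 0.5 and 2.99% of 0.25 were called. An adjusted p is harder to pass where fewer genes change, so these shares do not carry over to this comparison. Changes of 0.5 could be missed here too, as could smaller ones. Germ line genes were lower as a list (adjusted p 0.0077, with 0 passing and 4 fallen adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.76) and with the 5/2 libraries only (adjusted p 0.20), and no list passed by fry (germ line 0.73). Stress and hypoxia genes passed as higher with equal library totals (adjusted p 0.017 and 0.0082) and under quantile normalization (adjusted p 0.040 each), as did ribosomal protein genes under the latter (adjusted p 0.040). Each of these calls was lost with a correlation estimated in the same fit (adjusted p = 0.63 or more with an estimated correlation). Ddx4 stood at -0.43 ± 0.09 with an adjusted p of 0.39, and Lin28a at -0.40 ± 0.11 with a limma adjusted p of 0.50.

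Set against R595H/+, the R595H/R595H clones had Peg10 higher by 0.99 ± 0.14, Ntn1 by 0.79 ± 0.11, Abcd3 by 0.70 ± 0.07, Plxnb2 by 0.70 ± 0.09, Abca1 by 0.64 ± 0.09 and Trim71 by 0.53 ± 0.07 (SE, n = 3 clones against 3). Lefty2 fell by 0.84 ± 0.16, A2m fell by 0.79 ± 0.16, Rnf213 fell by 0.75 ± 0.11 and Hmga2, a chromatin protein gene and let-7 target, fell by 0.68 ± 0.13. Limma called 74 genes, 55 higher and 19 lower, with 1793 at an unadjusted p under 0.05, and clones did not overlap for 25.4% of genes against 10% by chance. Hypoxia and glycolysis genes were lower with 0 of 19 passing (0 risen and 5 fallen adjusted over the list alone), at an adjusted p of 1.0e-04 (adjusted p = 0.52 with an estimated correlation). Naive pluripotency genes were higher with 2 of 24 risen, Tet2 by 0.45 ± 0.07 and Klf4 by 0.36 ± 0.07 (3 adjusted over the list alone), at an adjusted p of 0.032 (adjusted p = 0.34 with an estimated correlation). By fry the naive list passed (adjusted p 0.033), hypoxia genes did not (0.26), and BMP and TGF-beta response genes passed as lower (0.045, against 0.13 by camera). The count was 7 without R595H/R595H C14, 3 with the mean of the Y-linked genes as a covariate and 19 (11 higher, 8 lower) with equal library totals. Alternatives took away the calls of Lefty2 and A2m 9 times each, of Klf4 8 times, of Hmga2 7 times and of Tet2 4 times. Of the called genes named for this comparison, 3 kept theirs in each alternative (Peg10, Abcd3 and Abca1).

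How alike were the deletion and the homozygous change? Ntn1, Plxnb2, Abcd3, Eda2r, Lama1 (0.52 ± 0.08 in Trim71-KO) and the ketone body enzyme gene Oxct1 (0.56 ± 0.06 and 0.60 ± 0.08) rose in both systems. Rnf213, Lin28a, the uridine phosphorylase gene Upp1 (fell by 0.44 ± 0.06 and fell by 0.44 ± 0.11) and the small GTPase gene Ralb (fell by 0.42 ± 0.07 and fell by 0.41 ± 0.09) were lower in both. In R595H/R595H the call of Upp1 was lost in 11 alternatives, that of Eda2r in 6, of Ralb in 4 and of Lin28a in 2, while the other 6 of these genes kept theirs in both systems. Of 9529 genes tested in both fits, 71 were called higher in both where chance gives 19.3, and 46 lower in both where chance gives 10.9. The 5 genes called in opposite directions, chosen for naming after their values were seen apart from Trim71, were Trim71, Pef1, Slc4a2 and Mier2, with Fut9 the one higher in Trim71-KO. Except for Trim71 these opposite calls were unstable: alternatives took away the Trim71-KO call of Pef1 11 times and of Slc4a2 12 times, and the R595H/R595H call of Mier2 13 times and of Fut9 11 times. With the replicate block the Trim71-KO calls of Pef1, Slc4a2 and Mier2 were lost (adjusted p 0.089, 0.074 and 0.069). Fold changes went together across genes with a Pearson r of 0.366 and a Spearman rho of 0.326; genes are not independent replicates.

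**Figure D3:**
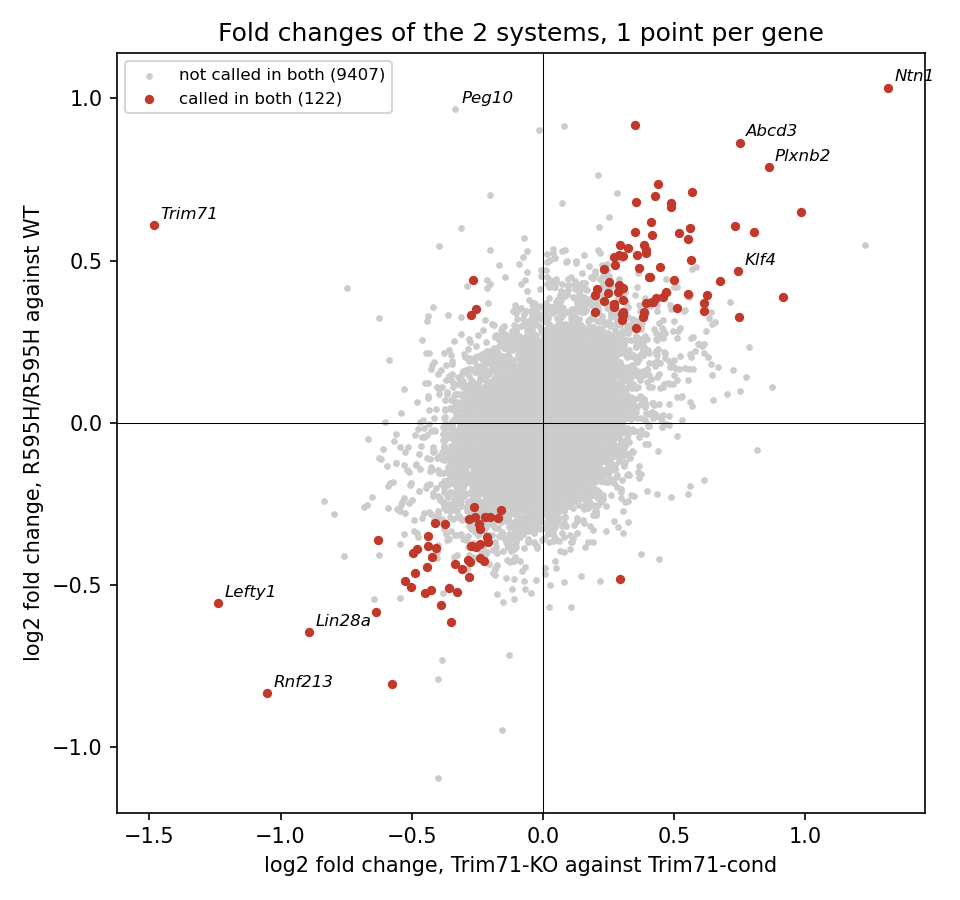
Log2 fold change of each of 9529 genes in Trim71-KO against Trim71-cond (x axis) and in R595H/R595H against WT (y axis), with the 122 genes called in both coloured. Of these, 71 lay higher in both, 46 lower in both and 5 in opposite directions.

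Genes called in one system shifted as a set in the same direction in the other, though most were not called there. The 878 genes higher in Trim71-KO had a median of 0.11 in R595H/R595H, 75.1% of them above 0 (camera p 1.3e-13, and 0.0070 with an estimated correlation). The 894 lower genes had a median of -0.10, with 73.0% below 0 (camera p 2.6e-10, and 0.0071 with an estimated correlation). In reverse, the 209 genes higher in R595H/R595H had a median of 0.17 in Trim71-KO with 86.1% above 0 (camera p 7.4e-19), and the 116 lower genes one of -0.16 with 83.6% below 0 (camera p 2.1e-13). In R595H/+ against WT the Trim71-KO sets had medians of 0.00 and 0.00, with 51.5% and 49.8% in the same direction (camera p 0.66 and 0.81). Fold changes in Trim71-KO and R595H/+ had an r of 0.016 across genes. The sets also shifted between R595H/R595H and R595H/+, which involves no WT clone, with medians of 0.11 (78.5% above 0, camera p 6.7e-15) and -0.10 (73.0% below 0, camera p 2.6e-11), and p of 0.0055 for each with an estimated correlation. The R595H/R595H and R595H/+ effects shared an r of 0.439, where unchanged groups against the same WT clones gave a median of 0.549 in 100 simulations, so that value says nothing of a shared effect.

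**Figure D4:**
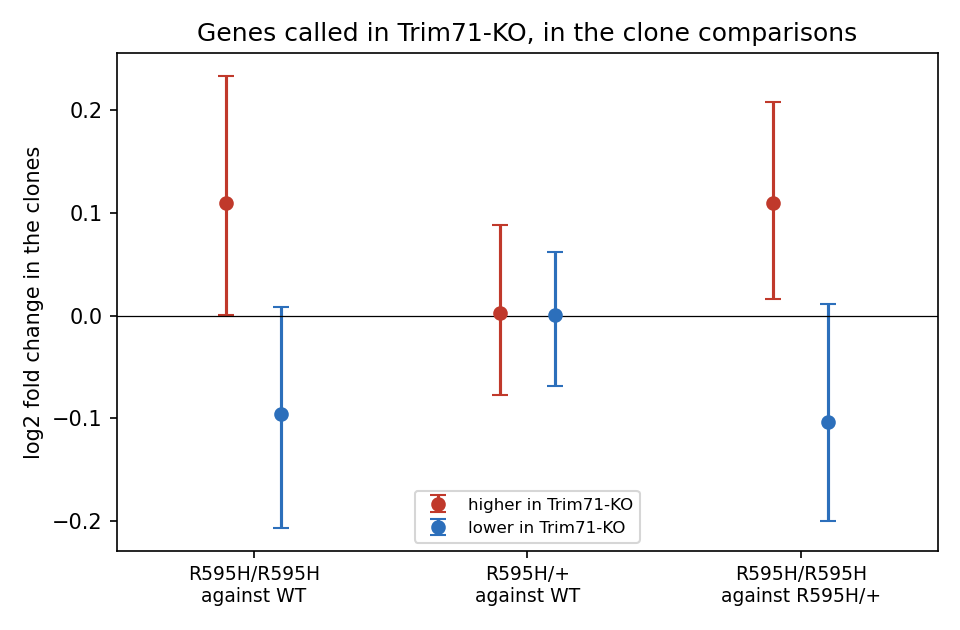
Median (point) and quartiles (bar) of the log2 fold change in the clone comparisons of the genes called higher and lower in Trim71-KO. The medians were 0.11 and -0.10 in R595H/R595H against WT, and 0.11 and -0.10 in R595H/R595H against R595H/+.

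The effects of the deletion and of the homozygous change were also tested for a difference, gene by gene. Ccr4 differed by 1.79 ± 0.16, Pros1 by 0.90 ± 0.16, Hook1 by 0.77 ± 0.13, Nfib by 0.76 ± 0.13 and the pluripotency factor Klf5 by 0.72 ± 0.11, each more positive in Trim71-KO. Trim71 differed by -2.09 ± 0.08, Peg10 by -1.30 ± 0.24, the metallothionein gene Mt1 by -0.78 ± 0.15, Sema5a by -0.78 ± 0.14, the polarity gene Pard3 by -0.65 ± 0.12, Maged1 by -0.63 ± 0.10 and Ccne1 by -0.52 ± 0.13. The call of the Ccne1 difference was lost in 14 alternatives. Limma called 136 of 9588 genes, 70 above 0 and 66 below, with 1666 at an unadjusted p under 0.05. S phase genes differed as a list by camera, at an adjusted p of 0.0070, with 0 above and 1 below of 22 (0 and 2 adjusted over the list alone), and the call was lost with an estimated correlation (adjusted p = 0.63) and was absent by fry (0.18). Stress genes, more negative in Trim71-KO, missed by camera (adjusted p 0.074, and 0.034 with equal library totals, where adjusted p = 0.85 with an estimated correlation) and passed by fry (0.025). The p53, naive pluripotency, neural progenitor and neuronal lists had adjusted p-values of 0.36, 0.50, 0.70 and 0.37 for the difference. The count was 40 without WT C7 and 213 without R595H/+ C21, and with each library scaled to the same total it was 100, of which 70 were above 0 and 30 below.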

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

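The distance test on Ccr4 and the minimum number of chemokine receptor genes for a verdict were chosen after the results were seen; the other tests in this part were chosen before.

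Trim71 transcript was lower in Trim71-KO and higher in R595H/R595H, and the effects differed by -2.09 ± 0.08 on the log2 scale (limma adjusted p 8.2e-17). With each library scaled to the same total the difference was -2.05. The totals, from 1.67e+06 (R595H/R595H C20) to 1.94e+06 (R595H/R595H C24), were too alike for that scaling to move it far. This test therefore cannot decide on other kinds of library scaling. A change of the whole chromosomal region is argued against by the other 14 genes tested within 2 Mb. Their median was 0.038 in R595H/R595H, from -0.14 to 0.17, where Trim71 rose by 0.61. What stays open is scaling of another kind, the genotype itself and whatever differed between the clones by descent. That the R595H protein may leave its own transcript at a higher level is a hypothesis that nothing here tested.

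Ccr4 rose in Trim71-KO, and its effect there exceeded that in R595H/R595H by 1.79 ± 0.16 (limma adjusted p 2.8e-08). A rise of the whole region is argued against by the other 14 genes tested within 1 Mb, whose median was 0.041 and whose highest value was 0.29, against 1.85 for Ccr4. Reads shared with other chemokine receptor genes stay open, because the table holds 3 of them with a median of -0.058, too few above the filter to decide. Transcription running from the altered locus into Ccr4, which starts 2216 bases beyond the 3' end of Trim71 on the same strand, may be a candidate explanation. Its position was known when that test was chosen and the table holds no values between genes, so the data cannot decide it.

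In total 25 of the 85 named genes had effects that differed between Trim71-KO and R595H/R595H in limma, some of them named because they differed. More positive in Trim71-KO were Pros1 (0.90), Hook1 (0.77), Fut9 (0.77), Nfib (0.76), Klf5 (0.72), Mbnl1 (0.52), Nr5a2 (0.45) and Trp53inp1 (0.43). More negative in Trim71-KO were Peg10 (-1.30), Sema5a (-0.78), Mt1 (-0.78), Slc4a2 (-0.70), Lefty1 (-0.68), Pard3 (-0.65), Col4a2 (-0.65), Maged1 (-0.63), Mier2 (-0.61), Pef1 (-0.60), Gadd45a (-0.60), Epha4 (-0.57), Abca1 (-0.55), Ccne1 (-0.52) and Sall4 (-0.39).

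A single library stood apart from the other libraries of its group in 7 of 118 groups of 4 values, where chance gives 5.9. Low values were Lin28a in Trim71-cond 3B (6.57), Ccne1 in Trim71-KO 2B (6.21), Aldoa in Trim71-KO 3B (10.09), Nefm in Trim71-cond 1A (3.55), Pef1 in Trim71-KO 3A (4.68), Slc4a2 in Trim71-cond 2B (4.11) and Fut9 in Trim71-cond 3A (7.84).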

How the results depend on the processing

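The covariates for Lars2 and for the mean of 4 Y-linked genes, and the list tests with equal library totals or recomputed median-of-ratios factors, were chosen after seeing the data; the other alternatives were planned. Fits of read counts with edgeR or DESeq2, and other added constants on the log scale, were not run, because the values cannot be turned back into reads. The inferred shrinkage of low values and the unknown depth limit what can be said of genes with low levels. The cause of each move in a count below was not tested, except that fewer genes or clones enter some fits.

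The Trim71-KO count stayed between 1291 and 1634 without each library in turn, was 1392 with the replicate block, and was 6 with a 2-fold minimum, against 1783. The R595H/R595H count of 328 was 176 at a mean of at least 50, 158 (72 higher, 86 lower) with equal library totals, 191 with the 5/2 libraries only, 1275 (671 higher, 604 lower) with 12 libraries as separate replicates, 564 with the Lars2 covariate, 134 with the Y-linked covariate and 1 with a 2-fold minimum. Without one clone it ran from 67 (C14) to 541 (C21), with 68 (C7), 73 (C5), 81 (C16), 171 (C15) and 208 (C24). The R595H/+ count of 0 became 22 with 12 libraries as separate replicates, which counts some clones more than once. The R595H/R595H against R595H/+ count of 74 was 115 with no filter, 37 at a mean of at least 50, 19 (11 higher, 8 lower) with equal totals, 124 (79 higher, 45 lower) with the clone as a random block, 1007 (532 higher, 475 lower) with separate replicates, 244 (150 higher, 94 lower) with Lars2, 3 with the Y-linked covariate and 0 with a 2-fold minimum. Without one clone it ran from 7 (C14, 6 higher and 1 lower) to 80 (C23), with 12 (C15), 21 (C16, 19 higher and 2 lower), 21 (C5), 22 (C21) and 34 (C24). The count of differing effects, 136, was 100 (70 above 0, 30 below) with equal totals and 3 with a 2-fold minimum. Without one sample it ran from 40 (C7) to 213 (C21), with 47 (C14), 133 (C20, 54 above 0 and 79 below), 73 (Trim71-cond 3A), 78 (Trim71-KO 3A), 71 (Trim71-cond 2B) and 71 (Trim71-KO 2B).

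The correlation of Trim71-KO and R595H/R595H fold changes lay between 0.311 (without WT C5) and 0.418 (without WT C7), at 0.355 with Lars2 and 0.329 with the Y-linked covariate. The Trim71 differences and the tests of called sets kept their direction and side of the threshold, except that Trim71 against R595H/+ lost its limma call with the Y-linked covariate (adjusted p 0.051). For named genes, 2142 of 2482 alternatives kept both, 337 lost the call and 3 gained one, and mt-Co1 was at 0 under quantile normalization. Of the named genes, 15 of 25 differences, 51 of 59 calls in Trim71-KO, 14 of 38 in R595H/R595H and 7 of 13 against R595H/+ kept their call without each sample in turn. The differences of Lefty1, Ccne1, Nr5a2, Sall4, Trp53inp1, Mier2, Epha4, Abca1, Gadd45a and Col4a2 did not. The replicate block took away the Trim71-KO calls of Kdm1a, Scn3a, Pef1, Slc4a2 and Mier2 and of no other named gene or list. Of 552 list alternatives, 493 kept both, 30 lost a call, mostly with an estimated correlation, and 16 gained one. In 13 a list past no threshold changed direction. With the 5/2 libraries only these were G2/M in R595H/R595H (0.955) and naive pluripotency (0.956), chromatin regulators (0.867) and S phase (0.982) in R595H/+. Under quantile normalization they were ribosomal proteins in R595H/R595H (0.225), chromatin regulators (0.941) and mitochondrial genes (0.977) in R595H/+, G2/M against R595H/+ (0.901), and Notch (0.985), ribosomal proteins (0.598) and lipid synthesis (0.893) for the difference. With equal library totals they were naive pluripotency (0.992) and TRIM71 targets (0.994) in R595H/+.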

Other observations

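The Lars2 covariate and the list tests with equal library totals were chosen after seeing the data, and the splits that part every code pair were not planned. The other tests in this part were chosen before.

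Between R595H/R595H and R595H/+ clones more lists passed than the comparison above names. Reported TRIM71 targets (1 risen and 0 fallen of 7, adjusted p 0.045) and immediate early and stress genes (0 of 16 passing, adjusted p 0.032) were higher as lists in R595H/R595H. Wnt response genes (0 of 7 passing, adjusted p 0.032), S phase genes (0 of 22 passing, adjusted p 0.044) and lipid and cholesterol synthesis genes (0 of 23 passing, adjusted p 0.044) were lower. With an estimated correlation the adjusted p was 0.34 for TRIM71 targets, 0.34 for stress genes, 0.42 for Wnt, 0.55 for S phase and 0.55 for lipid synthesis. By fry TRIM71 targets and stress genes passed (adjusted p 0.033 each), and Wnt (0.16), S phase (0.21) and lipid synthesis (0.24) did not. S phase and lipid synthesis also lost their calls under quantile normalization (adjusted p 0.096 and 0.083) and, with TRIM71 targets, with the 5/2 libraries only (adjusted p 0.089, 0.16 and 0.089). The p53 list passed under quantile normalization (adjusted p 0.049), and it (0.025) and endoderm genes (0.046) passed with equal library totals, calls lost in the same fits with an estimated correlation (adjusted p = 0.52 or more). Adjusted over the list alone, 2 and 0, 3 and 0, 0 and 3, 0 and 0, and 0 and 4 members rose and fell. Y-linked transcripts varied between clones of one genotype: the mean of 4 such genes was 5.27 in R595H/+ C21 and 4.02 in R595H/+ C23, and Ddx3y differed by -1.10 ± 0.99 between R595H/R595H and WT (limma adjusted p 0.58).

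The fold changes of Trim71-KO and R595H/R595H went together, with an r of 0.366 across genes. A shared trend with GC content and transcript length is argued against, since r was 0.431 once a smooth trend on both was removed, and the fold changes followed GC in opposite senses (r -0.206 in Trim71-KO and 0.210 in R595H/R595H). Ribosomal RNA carry-over read as Lars2 is argued against too, since r was 0.355 with the Lars2 value as a covariate in both fits. Of 35 splits of the conditional libraries only 1, the real one, gave an absolute r as large, though the highest other reached 0.341. With that value so near, and the share the smallest possible, chance in how these libraries were parted was unlikely but is not excluded. The clone contrast was held fixed there, so chance among the clones stays open. The 10 splits of the clones were too few to exclude it (real 0.366, highest other 0.317). A common effect of losing TRIM71 function may account for the rest, as a hypothesis, and differences in growth between cultures stay open because nothing recorded them.

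For the Trim71-KO count, chance in how the libraries were parted can be excluded. Only 1 of 35 splits, the real one with 1783 genes, called as many, and the highest other called 3. Among the 8 splits that part all 4 code pairs the highest other called 2. The labels name no clone for these libraries, so the splits cannot speak to other differences between the Trim71-cond and Trim71-KO cells. For the clones the 10 splits of each comparison are too few. The real R595H/R595H split called 328 and the highest other 0. The real split against R595H/+ called 74 and the highest other 0. In R595H/+ against WT the real split called 0 and the highest other 3, so that 10 of 10 called as many. For the difference of effects 2 of 100 reassignments of samples between the systems, the real one included, called as many as the 134 of the real assignment after centring. Such a count was rare, but the highest other called 229, so chance is not excluded. The reassignments also exchanged libraries of the conditional line with clone values, which may differ in spread.

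Stronger let-7 activity without TRIM71 was put forward as a hypothesis, since TRIM71 has been linked to microRNA silencing. Among 9468 genes with an annotated 3' UTR, the 1157 with a let-7 seed match had a mean log2 change in Trim71-KO that differed by -0.0138 from that of genes without one in the same length bins. The one-sided permutation p was 0.0141, and 0.0564 adjusted over 4 tests, so the result fails the correction. In R595H/R595H the difference was 0.00696 (p 0.894). Weaker activity of the miR-290 family, tested for a higher mean, gave -0.00217 in Trim71-KO (p 0.622) and -0.0221 in R595H/R595H (p 0.9997), the latter opposite to the prediction. Genes with only other forms of the site counted as having no match, so these values cannot decide on the activity of the family. For both families the permutations shuffled genes, which are not independent replicates, so their p-values do not measure spread between libraries or clones. The bins held UTR length and not GC content, which the fold changes followed (r -0.206 in Trim71-KO and 0.210 in R595H/R595H).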
